A study of Mus musculus with 8 samples.

How the data were processed

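Liver total RNA of 3 Me1 knockout and 5 wild-type littermate mice was measured on 2-colour arrays, 1 deposited column per mouse, against a pool of liver RNA from 5 wild-type mice. RNA was isolated on spin columns with DNase treatment and amplified with aminoallyl labelling, and Cy3 and Cy5 marked the 2 channels, per the labels. A dye swap was part of the profiling, per the series' design text; how the swapped arrays were merged into 1 column per mouse, the background correction and the normalization are not given in the sources used here. Whether the pool was made of the same 5 wild-type mice is not stated. Groups and mouse numbers came from the sample titles. Different mice are the replicates, and the mouse numbers do not pair the genotypes.

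The deposited values are log10 ratios, with 39556 probes and no missing value; 2 values lie at exactly -2, which is the lowest value of the table, and the highest is 1.34. Neither the base of the logarithm nor the direction of the ratio is stated with the values, so both were inferred. If the pool stands for the 5 wild-type mice, the mean ratio over them should be 1. Over the 300 probes that varied most, the median of that mean was 0.999 when the values were read as log10 of mouse over pool, 1.33 with the opposite sign and 0.968 as log2. Over the 100 most variable probes it was 0.991, 1.66 and 0.946. Among all 32 ways to turn single wild-type arrays, leaving none turned gave the smallest mean absolute deviation (0.0902, next 0.299, log2). This check does not reach the knockout arrays, whose direction rests on titles and dyes of the same form as those of the wild types. Over all probes, 3 pairs of arrays correlated below -0.3: wild-type mice 22 and 26 (r = -0.459), wild-type mice 14 and 22 (r = -0.322), and wild-type mouse 14 with knockout mouse 33 (r = -0.394). A pool made of the same 5 mice would itself give negative correlations between wild types, whose median r was -0.12, so those 2 pairs do not speak against the direction found. The wild-type ratios to such a pool nearly cancel, so a knockout would tend to correlate negatively with some wild types in either direction. Knockout mouse 33 had r = -0.3937 and -0.2896 with wild-type mice 14 and 26. With mice 15, 21 and 22 it had 0.0731, 0.2595 and 0.2642. Given such a pool, its pair with mouse 14 tells nothing about the direction. Because the check does not reach them, the direction of the knockout arrays is not settled. The counts are therefore also given with the sign of the knockout arrays turned. Turning that sign mirrors the knockout values at 0, so a difference changes its sign only where the wild-type mean is close enough to 0. The Me1 difference would stay positive, since the wild-type mean of -0.31 lies further from 0 than the knockout mean of -0.22. The median log10 ratio was 0.0014, 0.0001, 0.0016, -0.0052 and 0.0052 in wild-type mice 14, 15, 21, 22 and 26, and 0.0042, 0.0075 and 0.0045 in knockout mice 27, 31 and 33, so centring on the median was near 0 in every array. No 2 columns were identical.

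Probes were named through the platform annotation given with the series. Of the 39556 probes, 23283 had 1 gene symbol, none had several and 16273 had none. Symbols were brought up to date through a table of the mouse assembly GRCm38.p6: 16574 were current, 6594 were updated through a synonym and 115 were kept as listed. That table served for names and for the order of genes on chromosomes only. Values were multiplied to the log2 scale, and probes of 1 symbol were averaged, which gave 19896 named genes; with the unnamed probes kept singly, 36169 features were tested. Gene symbols with more than 1 probe numbered 2869.

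Knockout and wild type were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, 1 value per mouse and equal weights, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Wild-type arrays were tested against the pool as their mean log ratio against 0, a test whose outcome is fixed if the pool holds the same mice. For Me1 an exact permutation test ran over the 56 splits of the 8 mice. The 39 gene lists were tested on the named genes with camera at a preset correlation of 0.01, all with at least 5 measured members, and beside it with camera at an estimated correlation and with fry. Adjusted p for lists runs over the 39 lists. Values adjusted over the list alone use Benjamini-Hochberg within 1 list. In simulated data of the same size, with 200 features changed, the fit recovered 52% of changes of 0.5, 88% of changes of 1 and 96% of changes of 2 on the log2 scale, and 7.43% of its calls were false, 13 of 175. A simulated list of 30 genes shifted by 0.3 gave a p of 9.05e-40 by camera, and an unshifted one 0.695. The simulated genes varied independently of one another, while members of real lists did not, with an estimated correlation of 0.661 in cholesterol synthesis. The simulation therefore cannot tell how camera at the preset correlation behaves on such lists.

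Genes named in the text followed a rule fixed beforehand: Me1; up to 12 rising and 12 falling genes with the largest differences among those past the threshold with 1 symbol and all 3 knockout values outside the wild-type range, of which there were 3 and 3; and in each list the 3 members with the smallest unadjusted p. Members named beyond these 3 were chosen after their values were seen, as were all other genes of the closing section: in the cholesterol list Idi1, Cyp51, Nsdhl, Hmgcs1 and Srebf2, in the fatty acid list Fads1, Fads2 and Elovl2, in the acute phase list Mt2, Saa1, Saa3 and Hp, in the pyruvate cycle Slc25a10, and in the endothelial list Vwf. The probes of Pvalb went in opposite directions (0.12 and -0.42), and those of Zfp626 and Pgls differed as stated. Probes also differed in size for Manf (0.58 and 0.08), Ogdh (-0.04 and -0.32), Cel (0.30 and 0.07), Ahsg (0.13 and 0.35), Cyp2b10 (-0.23 and -0.53), Krt7 (0.14 and 0.05), Acpp (-1.15 and -0.36) and Ppp2r3a (-0.50, -0.33, -0.07 and -0.02).

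Alternatives fixed beforehand were array medians set to 0, quantile normalization, robust moderation, array weights, each probe tested separately (the probe with the smallest p standing for a gene), named genes alone, removal of the least variable features or of those at the limits of the table, a per-gene test without moderation, the knockout arrays alone against the pool, leaving out each mouse, and other thresholds. Added after the data were seen were the turned sign, leaving out both arrays of widest spread (wild-type mouse 22 and knockout mouse 33), an exact permutation of each list's mean, and the scans of gene order, which used windows of 50 genes, an unadjusted p of 0.01 and 1000 shuffles (numpy 2.4.6, scipy 1.17.1). Windows of 20 and 50 genes and p values of 0.001 and 0.01 were looked at before that choice. The rule for genes that split the mice into 2 clusters was also set after the data were seen.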

Results

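Liver RNA was profiled on 2-colour expression arrays from 3 mice labelled as Me1 knockouts and from 5 littermates labelled as wild type. Me1 encodes the cytosolic malic enzyme, which turns malate into pyruvate and yields NADPH for the synthesis of fatty acids. Each mouse's RNA was set against a common pool of liver RNA from 5 wild-type mice, so every value is a log ratio of a mouse to that pool. The mice are named here by the numbers in their labels, 14, 15, 21, 22 and 26 for the wild types and 27, 31 and 33 for the knockouts. The spread (SD) of the log2 ratios over 39556 probes was 0.127 in wild-type mouse 14, 0.134 in 15, 0.139 in 21, 0.291 in 22 and 0.191 in 26. It was 0.185 in knockout mouse 27, 0.215 in 31 and 0.273 in 33. The array of wild-type mouse 22 thus had the widest spread of all 8. The number of arrays limits the precision, and spot brightness was not used here. Differences below are knockout minus wild type on the log2 scale, given with the standard error of the limma fit, and n is 3 knockout and 5 wild-type mice throughout.

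The targeted gene was read by 1 probe, listed under the older symbol Mod1. Its log2 ratio to the pool was -0.22 ± 0.90 (SD, n = 3) in the knockout and -0.31 ± 1.07 (SD, n = 5) in the wild type. The single values were 0.82, -0.81 and -0.68 in knockout mice 27, 31 and 33, and 0.82, -0.64, -0.70, -1.73 and 0.70 in wild-type mice 14, 15, 21, 22 and 26. The difference of 0.09 ± 0.64 had a 95% confidence interval from -1.38 to 1.55, and an exact two-sided permutation test over the 56 splits of the mice gave p = 0.875, where the smallest p possible is 0.0179. Me1 signal therefore did not separate the genotypes. Where this probe lies relative to the altered part of the gene was not given, and a probe outside that part checks nothing about the labels.

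**Figure D1:**
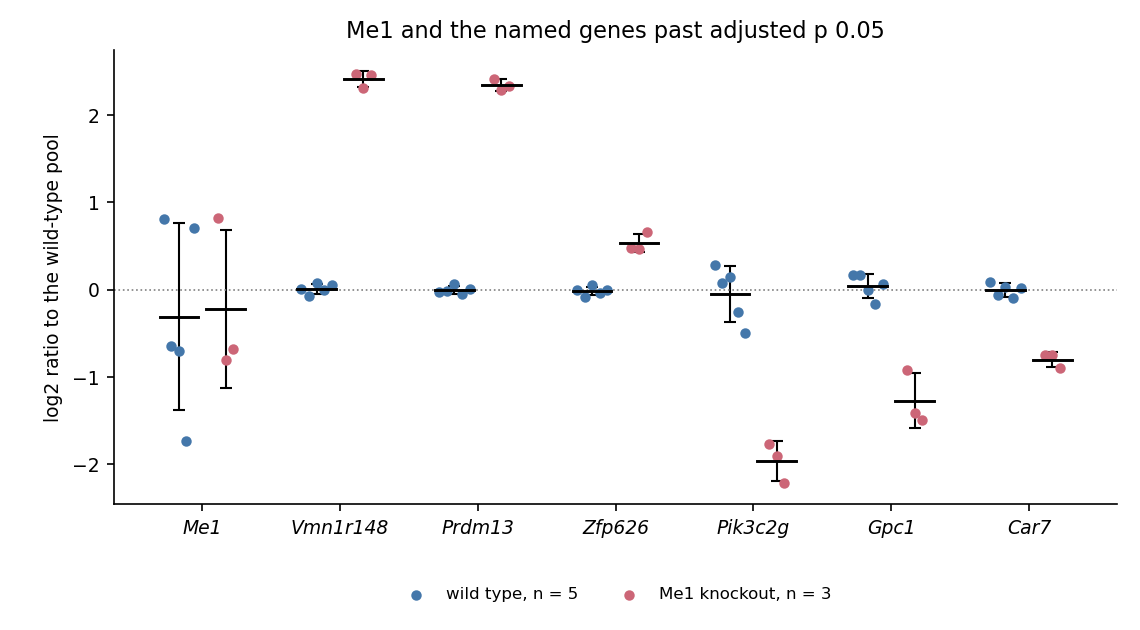
The log2 ratio to the wild-type pool (vertical axis) of Me1 and of the 6 named genes past adjusted p 0.05, with 1 point per mouse, blue for the 5 wild types and red for the 3 knockouts; bars are means and whiskers 1 SD. Me1 values overlap between genotypes, while in each of the other 6 genes the 3 knockouts lie outside the wild-type range, as the naming rule required.

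The main comparison set the 3 mice labelled as knockouts against the 5 wild types. The 1 probe listed for Prdm13, a zinc finger transcription factor known from the developing nervous system, rose 5.08-fold (log2 difference 2.34 ± 0.05, adjusted p = 7.87e-07). Its log2 ratio went from 0.00 ± 0.05 (SD) in the wild type to 2.34 ± 0.06 in the knockout. Vmn1r148, listed for 2 probes and a member of a large family of near-identical pheromone receptor genes, gave a log2 difference of 2.40 ± 0.06 (adjusted p = 1.22e-06). Which family member these probes read is uncertain. In knockout mice 27, 31 and 33 the Prdm13 values (2.41, 2.28 and 2.34) lay close to those of Vmn1r148 (2.47, 2.31 and 2.46). Probe sequences were not used, so what the Prdm13 probe reads is uncertain too. Among the genes that fell were Pik3c2g, a class II phosphoinositide 3-kinase of the liver, by 3.77-fold (-1.91 ± 0.19, adjusted p = 0.0265), and Gpc1, a cell-surface heparan sulphate proteoglycan, by 2.49-fold (-1.32 ± 0.14, adjusted p = 0.0364). Car7, a cytosolic carbonic anhydrase, fell by 1.74-fold (-0.80 ± 0.06, adjusted p = 0.00602). Zfp626, a zinc finger gene, rose by 0.55 ± 0.06 as the mean of 3 probes (adjusted p = 0.0364), but its probes disagreed: 1 gave 1.44 ± 0.12 and the others 0.07 ± 0.05 and 0.13 ± 0.11. Each of these 6 genes had all 3 knockout values outside the range of the 5 wild-type values. The rule for naming genes required this, and all 6 named genes past the threshold met it.

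In all, 10 of 36169 features passed adjusted p 0.05 in limma with Benjamini-Hochberg adjustment, 5 higher and 5 lower in the knockout. Besides the 6 named genes these were 4 probes with no gene symbol: 10024397327 and 10028673637 rose by 1.16 ± 0.07 and 1.17 ± 0.10, and 10024403096 and 10024409658 stood at -1.39 ± 0.07 and -1.29 ± 0.10. At an unadjusted p of 0.05 the count was 3355 features (9.28%). No overlap between the 3 knockouts and the 5 wild types was seen in 2607 features (7.21%). Over all splits of the 8 mice that share averages 3.57%. It was not counted for the other splits one by one, so no excess can be read from it. The unadjusted count does not set the genotypes apart, since 6 other splits of the 8 mice gave more features at an unadjusted p of 0.05, up to 7260 for wild-type mouse 22 with knockout mice 31 and 33. The count rested on single mice: it was 65 without wild-type mouse 22, 18 without wild-type mouse 26, 17 without knockout mouse 27 and 6 without wild-type mouse 14. With each mouse left out in turn, Pik3c2g and Gpc1 passed in only 2 of the 8 fits and Zfp626 in 1, with adjusted p up to 0.144, 0.172 and 0.158. Prdm13, Vmn1r148 and Car7 passed in all 8. The direction of the ratios was inferred and not stated; with the sign of the knockout arrays turned, 8 features passed.

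Among 39 gene lists fixed before the data were examined, 18 passed adjusted p 0.05 by limma's camera with its preset correlation of 0.01, 7 higher and 11 lower in the knockout. None of the 39 lists passed when the correlation between its members was estimated, with a lowest adjusted p of 0.525. None passed by fry, where the lowest was 0.0665. Unadjusted p under 0.05 was reached by 1 and 5 lists. The estimated setting raised p even for adipocyte genes, whose estimated correlation of 0.0117 was near the preset. Its adjusted p therefore reflects more than the correlation between members. With the sign of the knockout arrays turned, 17 lists passed, none of them in the direction given here. In all of the 18 but cholesterol synthesis, at least 1 wild-type median lay within or beyond the range of the knockout medians. With the sign turned this holds for all but cholesterol synthesis, ribosomal proteins and Kupffer cell markers. No member of any list passed adjusted p 0.05 over all features. Counts that passed when adjusted over the list alone are given with each list. In fry's test for change in either direction, 5 lists passed: acute phase proteins (adjusted p = 0.00232), endothelial markers (0.00232), fatty acid and triglyceride synthesis (0.00638), pyruvate, malate and citrate cycling (0.0156) and cholesterol synthesis (0.0271).

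**Figure D2:**
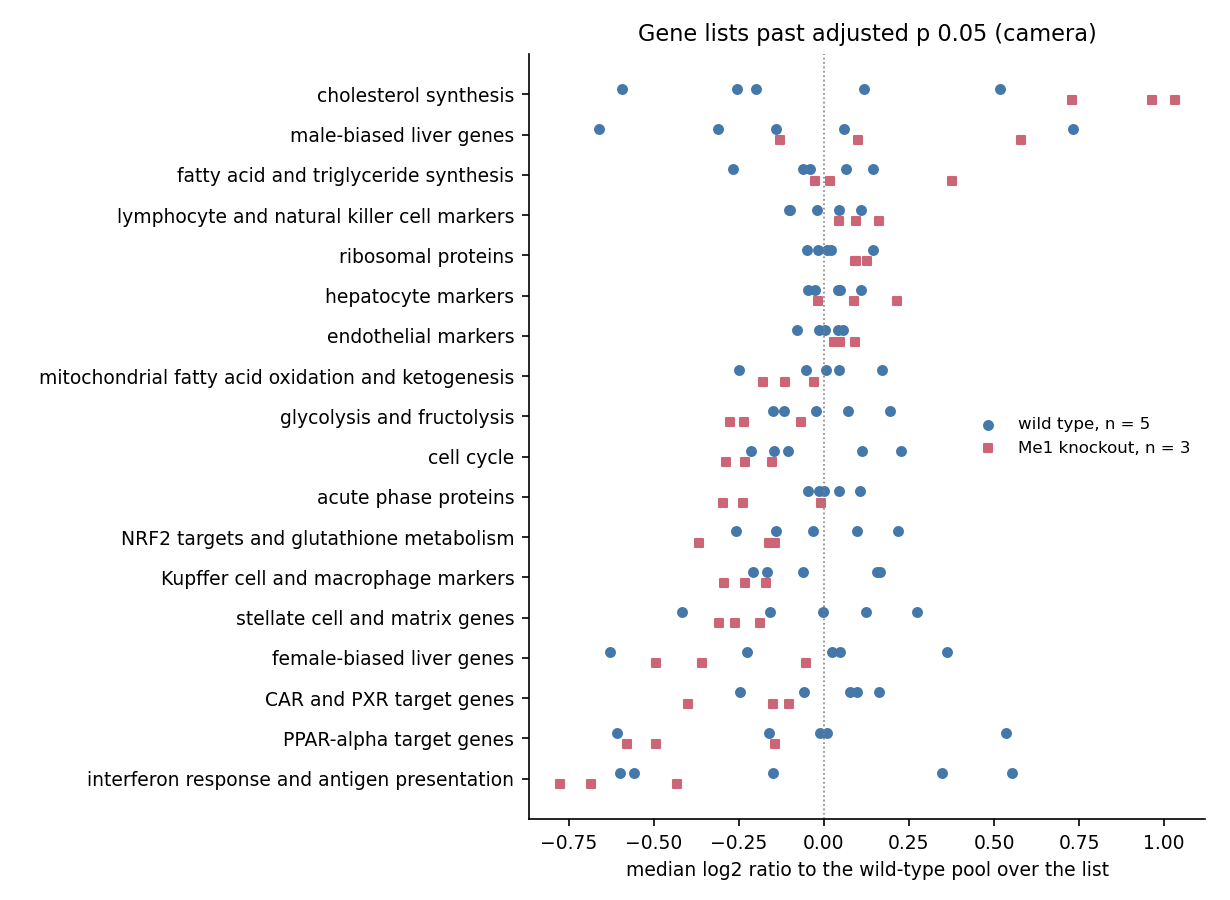
The median log2 ratio to the wild-type pool over the members of a list (horizontal axis) for the 18 gene lists past adjusted p 0.05 by camera with its preset correlation, with 1 point per mouse, blue circles for the 5 wild types and red squares for the 3 knockouts. Cholesterol synthesis is the only one of these lists in which all 3 knockouts, between 0.73 and 1.03, lie outside the range of the 5 wild types, between -0.59 and 0.52; with the knockout sign turned, ribosomal and Kupffer genes would separate too.

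Genes of cholesterol synthesis were higher in the knockout. All 19 measured members had a positive difference, with a median of 0.98 and a range from 0.04 to 1.69. Of these, 17 rose when adjusted over the list alone, and 0 passed over all features. Idi1, which isomerises isopentenyl diphosphate, stood at 1.69 ± 0.48, the lanosterol demethylase Cyp51 at 1.54 ± 0.35, and Nsdhl, which removes a sterol methyl group, at 1.44 ± 0.37. The 3 members with the smallest p were the sterol isomerase Ebp at 0.45 ± 0.07, the mevalonate pathway kinase Pmvk at 1.24 ± 0.25 and the sterol reductase Tm7sf2 at 1.05 ± 0.22. Hmgcs1 and Srebf2, the transcription factor of the pathway, were the 2 members that did not pass over the list alone. The Srebf2 difference was positive through knockout mouse 27 (0.34) only, as mice 31 and 33 had 0.03 and -0.21 against a wild-type mean of 0.01. The list passed by camera (adjusted p = 2.84e-17), but not with an estimated correlation of 0.661 between members (adjusted p = 0.525 with an estimated correlation, 0.0362 unadjusted). The mean over the list was 0.95, and it lay between 0.83 and 1.11 when any 1 mouse was left out.

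**Figure D3:**
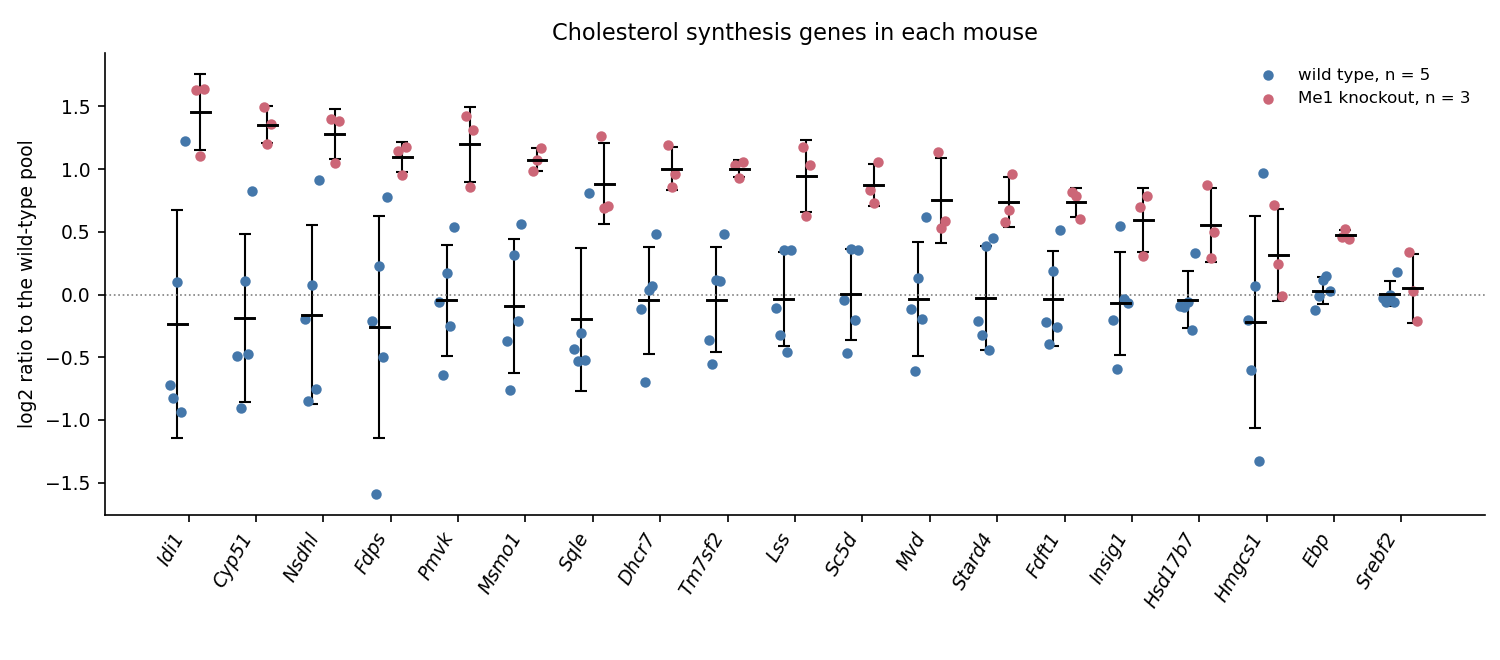
The log2 ratio to the wild-type pool (vertical axis) of the 19 measured cholesterol synthesis genes in each mouse, ordered by the difference between genotypes, with blue points for the 5 wild types and red points for the 3 knockouts; bars are means and whiskers 1 SD. The differences run from 1.69 for Idi1 to 0.04 for Srebf2, and wild-type mouse 26 has values close to the knockouts in several genes.

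Fatty acid and triglyceride synthesis genes were higher on balance, with 21 of 30 members above and 9 below 0 and a median of 0.17 (camera adjusted p = 0.0168; adjusted p = 0.525 with an estimated correlation). Adjusted over the list alone, 5 members rose and 1 fell, and none passed over all features. The list rested on knockout mouse 27: its median was 0.38 in that mouse and -0.03 and 0.02 in the other knockouts, and without mouse 27 the mean fell from 0.18 to 0.04 and the call ended (adjusted p = 0.284). It also ended without wild-type mouse 21 (adjusted p = 0.0502), with array weights (0.173) and for the knockout arrays against the pool (0.0823). The acetate-activating enzyme Acss2 stood at 1.02 ± 0.17, the phosphatidate phosphatase Lpin1 at 0.95 ± 0.19 and the desaturases Fads1 and Fads2 at 0.78 ± 0.23 and 0.64 ± 0.16, with the elongase Elovl2 at 0.76 ± 0.17. The member that fell was the monoacylglycerol acyltransferase Mogat1, at -2.51 ± 0.48, 5.68-fold lower in the knockout. Among the adipocyte genes Cidea stood at -3.26 ± 0.56, Cidec at -2.62 ± 0.85 and the lipoprotein lipase gene Lpl at -0.52 ± 0.14. Cidec did not pass over the list alone, and its value of -2.87 in wild-type mouse 22 lay within the knockout range of -3.75 to -2.31. Of 13 adipocyte genes, 8 were lower and 5 higher with a median of -0.30, Cidea and Lpl fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.0696), though it did in 5 refits, among them without the least variable features (0.0175), and in the opposite direction with the sign turned (0.0415). Of 23 apolipoprotein and lipoprotein genes, 8 were higher and 15 lower (median -0.03, adjusted p = 0.533), with Lpl first by p, Apoa4 at -1.98 ± 0.58 and Apoa5 at -0.33 ± 0.14.

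Target genes of the fatty acid receptor PPAR-alpha were lower, in 23 of 28 members, with a median of -0.36 (camera adjusted p = 0.003; adjusted p = 0.525 with an estimated correlation), and none passed over the list alone. The aldehyde dehydrogenase Aldh3a2 stood at -0.82 ± 0.24, the fatty acid transporter Cd36 at -1.15 ± 0.39 and the pantetheinase Vnn1 at -1.34 ± 0.45. Wild-type mice spread as widely as the genotypes differed here, since the median over the list was -0.61 in wild-type mouse 22 and 0.53 in mouse 26, against -0.14, -0.49 and -0.58 in the knockouts. The mean went from -0.42 to -0.26 without mouse 26. Mitochondrial fatty acid oxidation genes were lower in 14 of 17 members, with a median of -0.09 (adjusted p = 0.0266; adjusted p = 0.607 with an estimated correlation), none over the list alone. That call ended without wild-type mouse 15 or 26 and without knockout mouse 27 or 33 (adjusted p up to 0.175), and without the least variable features (0.0622). The median of wild-type mouse 22, -0.25, lay below every knockout. Acads stood at -0.16 ± 0.06, the carnitine carrier Slc25a20 at -0.45 ± 0.17 and Cpt2 at -0.28 ± 0.12.

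The lists for other routes to NADPH did not pass by camera. Of 10 NADPH-producing enzymes besides Me1, 4 were higher and 6 lower (median -0.01, adjusted p = 0.834). Aldh1l1 stood at 0.35 ± 0.11, Idh1, the cytosolic isocitrate dehydrogenase, at 0.29 ± 0.10 and Idh2 at -0.24 ± 0.15. Of 9 pentose phosphate genes, 4 were higher and 5 lower (median -0.03, adjusted p = 0.887). Taldo1 stood at -0.19 ± 0.10, Pgls at 0.10 ± 0.05 and Prps1 at 0.10 ± 0.07; the 2 Pgls probes gave 0.20 and 0.00. In the cycle of pyruvate, malate and citrate that Me1 belongs to, 10 of 16 genes were higher and 6 lower (median 0.03, adjusted p = 0.256). The mitochondrial carriers Slc25a11 and Slc25a1, for oxoglutarate and citrate, stood at 0.13 ± 0.04 and 0.30 ± 0.09, and the cytosolic aspartate aminotransferase Got1 at 0.41 ± 0.13, while the dicarboxylate carrier Slc25a10 stood at -0.56 ± 0.21. No member of these 3 lists passed over the list alone, and none of the 3 passed by camera. In fry's test for change in either direction, the pyruvate, malate and citrate list passed (adjusted p = 0.0156). The NADPH and pentose phosphate lists did not pass that test (0.237 and 0.703).

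In carbohydrate metabolism, glycolysis and fructolysis genes were lower in 16 of 17 members, with a median of -0.18 (camera adjusted p = 0.0159; adjusted p = 0.525 with an estimated correlation). The call ended without knockout mouse 31 (adjusted p = 0.0506). The member that passed over the list alone went the other way: Pfkfb1, the liver enzyme that sets fructose 2,6-bisphosphate, rose by 0.49 ± 0.09, while Pfkl stood at -0.27 ± 0.08 and Ldha at -0.26 ± 0.12. Of 19 genes of gluconeogenesis, 7 were higher and 12 lower (median -0.08, adjusted p = 0.27), with the mitochondrial Pck2 at -0.55 ± 0.11, which fell when adjusted over the list alone, Got1 at 0.41 ± 0.13 and the cytosolic Pck1 at -0.46 ± 0.16. Of 11 glycogen genes, 1 was higher and 10 lower (median -0.07, adjusted p = 0.265). Ppp1r3c stood at -0.57 ± 0.22, Gyg at -0.32 ± 0.14 and Gys2 at 0.33 ± 0.15. Insulin and growth hormone signalling genes had 13 of 19 members higher and 6 lower (median 0.08, adjusted p = 0.057). The list passed in 6 refits, among them with array medians at 0 (adjusted p = 0.0306) and without knockout mouse 27 (0.00731), and its mean of 0.21 ran from 0.11 to 0.35 with 1 mouse left out. Stat5a stood at -0.48 ± 0.16, Irs2 at 0.58 ± 0.22 and Foxo3 at 0.15 ± 0.06.

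Acute phase proteins, which the liver secretes in inflammation, were lower in 18 of 29 members and higher in 11, with a median of -0.19 and a mean of -0.44 (camera adjusted p = 2.66e-04; adjusted p = 0.525 with an estimated correlation). The call ended without knockout mouse 27 (adjusted p = 0.0537) and with array weights (0.0649). Adjusted over the list alone 7 members fell and none rose. Orm2 stood at -2.01 ± 0.33, the iron-siderophore binding protein Lcn2 at -1.79 ± 0.23 and the metallothionein Mt2 at -1.79 ± 0.49. The serum amyloids Saa2, Saa1 and Saa3 stood at -1.39 ± 0.26, -1.27 ± 0.31 and -1.10 ± 0.30, and haptoglobin, Hp, at -1.06 ± 0.23. Saa1 and Saa2 are near-identical in sequence, so their separate values are uncertain. Interferon response and antigen presentation genes were lower in 27 of 29 members, with a median of -0.58 (adjusted p = 2.20e-05; adjusted p = 0.525 with an estimated correlation), none over the list alone. The call ended without both arrays of widest spread, wild-type mouse 22 and knockout mouse 33 (adjusted p = 0.0724). Cxcl10 stood at -1.37 ± 0.47, Tap1 at -0.55 ± 0.21 and Irgm1 at -0.69 ± 0.27. The wild-type mice were spread widely in this list, with medians of 0.35 and 0.55 in mice 14 and 22 and of -0.56 and -0.60 in mice 15 and 26, against -0.43, -0.69 and -0.78 in the knockouts.

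Markers of Kupffer cells and macrophages were lower alongside these lists, in 22 of 27 members, with a median of -0.18 (adjusted p = 0.00955; adjusted p = 0.525 with an estimated correlation). The call ended without wild-type mouse 22 (adjusted p = 0.0713), without knockout mouse 27 (0.195), with quantile normalization (0.073) and without both widest arrays (0.0915). Lgals3 stood at -0.80 ± 0.24 and Mpeg1 at -0.64 ± 0.21, but the integrin gene Itgam at 0.48 ± 0.19. Neutrophil markers did not pass (4 of 13 higher and 9 lower, median -0.08, adjusted p = 0.158). They passed without knockout mouse 31 (adjusted p = 0.0444). Camp stood at -0.53 ± 0.21, Ngp at -0.46 ± 0.19 and S100a8 at -0.32 ± 0.13. Lymphocyte and natural killer cell markers were higher in 18 of 22 members, with a median of 0.11 (adjusted p = 0.00113; adjusted p = 0.525 with an estimated correlation), among them Jchain at 0.34 ± 0.12, Cd4 at 0.38 ± 0.14 and Cd79a at 0.13 ± 0.05. The mean of the lymphocyte list went from 0.12 to 0.07 without knockout mouse 31. No member of these 3 lists passed over the list alone.

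Matrix genes of stellate cells were lower in 19 of 21 members, with a median of -0.27 (adjusted p = 8.43e-04; adjusted p = 0.525 with an estimated correlation). Wild-type mouse 22 had a median of -0.42, below every knockout (-0.31 to -0.19). The collagens Col1a2 and Col5a2 stood at -0.83 ± 0.29 and -0.60 ± 0.23 and the collagen crosslinking enzyme Lox at -0.21 ± 0.08. Cell cycle genes were lower in 21 of 26 members, with a median of -0.21 (adjusted p = 2.66e-04; adjusted p = 0.525 with an estimated correlation). The replication helicase subunits Mcm2 and Mcm5 stood at -0.59 ± 0.17 and -0.22 ± 0.07 and cyclin D1, Ccnd1, at -0.58 ± 0.18. Neither list had a member past adjusted p 0.05 over the list alone. Endothelial markers went both ways, 11 of 17 higher and 6 lower, with a median of 0.09 (adjusted p = 0.0177; adjusted p = 0.525 with an estimated correlation). The call ended without wild-type mouse 22 (adjusted p = 0.0807), without knockout mouse 31 (0.101) and for the knockout arrays against the pool (0.0529). Fcgr2b of the liver sinusoid rose by 0.44 ± 0.09, and the receptors Kdr and Flt1 by 0.21 ± 0.06 and 0.24 ± 0.06, when adjusted over the list alone, where Vwf fell (-0.39 ± 0.11). Hepatocyte markers had 12 of 18 members higher and 6 lower, with a median of 0.09 (adjusted p = 0.0407; adjusted p = 0.525 with an estimated correlation), none over the list alone. That call ended in 4 of the 8 fits with 1 mouse left out, with adjusted p up to 0.324 without knockout mouse 31, and without both widest arrays (0.155). Ahsg stood at 0.24 ± 0.10, Apoa1 at 0.14 ± 0.07 and Cyp2e1 at 0.17 ± 0.09. Cholangiocyte markers did not pass (4 of 11 higher and 7 lower, median -0.01, adjusted p = 0.883). Aqp1 stood at 0.22 ± 0.06, Epcam at -0.24 ± 0.09 and Krt7 at 0.09 ± 0.04.

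Among genes of detoxification, 20 of 26 targets of the nuclear receptors CAR and PXR were lower, with a median of -0.26 (adjusted p = 0.00211; adjusted p = 0.525 with an estimated correlation). The mean went from -0.31 to -0.18 without knockout mouse 33, and the median of wild-type mouse 22, -0.25, lay below those of knockout mice 27 and 31 (-0.10 and -0.15). Cyp3a16 fell by 0.46 ± 0.08 on the log2 scale when adjusted over the list alone, Gadd45b stood at -0.55 ± 0.15 and Cyp2b10 at -0.38 ± 0.13. Targets of NRF2 and glutathione genes were lower in 27 of 34 members, with a median of -0.15 (adjusted p = 2.66e-04; adjusted p = 0.525 with an estimated correlation), none over the list alone. Gss stood at -0.53 ± 0.13, Srxn1 at -0.60 ± 0.18 and Gpx4 at -0.48 ± 0.15. Female-biased liver genes were lower in 18 of 24 members, with a median of -0.20 (adjusted p = 0.0304; adjusted p = 0.578 with an estimated correlation), led by Cyp3a16, which passed over the list alone, Cyp2b10 and Cyp3a41a (-0.82 ± 0.30). The female-biased call ended without wild-type mouse 15 or 26 and without knockout mouse 33, where the mean went from -0.30 to -0.05 (adjusted p = 0.338). It also ended with array medians at 0 (adjusted p = 0.0714), with quantile normalization (0.115) and without the least variable features (0.0586). Wild-type mouse 22 had a median of -0.63, below the knockouts at -0.05, -0.36 and -0.49. The sequences of the Cyp3a family are close to one another, so which member a probe reads is uncertain. The female-biased list shares Cyp2b9, Cyp2b10, Cyp2b13, Cyp3a16, Cyp3a41a, Cyp3a44 and Cyp2a4 with the CAR and PXR list. It shares Acot3, Cyp4a10 and Cyp4a14 with the PPAR-alpha list. These calls are therefore not separate results. Male-biased liver genes were higher in 13 of 19 members, with a median of 0.16 (adjusted p = 0.025; adjusted p = 0.658 with an estimated correlation), none over the list alone. The male-biased call ended in 4 of the 8 fits with 1 mouse left out, with an adjusted p of 0.601 without knockout mouse 33, for the knockout arrays against the pool (0.169) and without both widest arrays (0.0709). Nudt7 stood at 1.10 ± 0.27, Cib3 at 0.36 ± 0.13 and the organic anion transporter Slco1a1 at 2.31 ± 0.91, with wild-type Slco1a1 values from -3.08 to 1.18. The medians of this list ran from -0.66 in wild-type mouse 26 to 0.73 in wild-type mouse 22, a wider range than in the knockouts, which ran from -0.13 to 0.58. Genes of the sex chromosomes did not pass (4 of 5 higher, median 0.08, adjusted p = 0.392). Zfy2 stood at 0.08 ± 0.04, Xist at -0.11 ± 0.10 and Zfy1 at 0.10 ± 0.11.

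Ribosomal protein genes were higher in 55 of 65 members by a small amount, with a median of 0.08 (adjusted p = 2.34e-05; adjusted p = 0.525 with an estimated correlation), none over the list alone. Rpl10 stood at 0.20 ± 0.06, Rpl22l1 at 0.70 ± 0.21 and Rpl35a at 0.20 ± 0.06. Wild-type mouse 22 had a median of 0.15, above every knockout (0.09 to 0.13). The median over all features was 0.01. Oxidative phosphorylation subunits were split evenly, 38 higher and 39 lower, with a median of -0.00 (adjusted p = 0.692). Cox6b1 stood at 0.33 ± 0.09, Cox7a1 at -0.38 ± 0.12 and Uqcrq at 0.15 ± 0.05. Citric acid cycle genes were higher in 12 and lower in 10 of 22 members (median 0.02, mean -0.02, adjusted p = 0.827). Ogdh stood at -0.18 ± 0.06, Dlst at -0.27 ± 0.11 and Idh3a at -0.21 ± 0.09. Bile acid genes were higher in 13 of 19 members (median 0.08, adjusted p = 0.163), with the bile acid importer Slc10a1 at 0.36 ± 0.09, the phospholipid exporter Abcb4 at -0.48 ± 0.13 and Cyp27a1 at 0.54 ± 0.19. Urea cycle and amino acid genes were higher in 14 and lower in 12 of 26 members (median 0.03, adjusted p = 0.694). Agxt stood at 0.65 ± 0.24, Arg1 at 0.21 ± 0.08 and Bhmt at -0.28 ± 0.12.

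In the stress and clock lists, unfolded protein and integrated stress response genes were higher in 14 and lower in 9 of 23 members (median 0.09, adjusted p = 0.172). The list passed in 4 refits, among them with quantile normalization (adjusted p = 0.0275) and without wild-type mouse 22 (0.0386). Atf3 fell when adjusted over that list alone (-0.62 ± 0.14), while Xbp1 stood at 0.55 ± 0.14 and Manf at 0.33 ± 0.14. Heat shock genes did not pass (5 of 13 higher, median -0.03, adjusted p = 0.827). Hspb1 stood at -0.68 ± 0.19, Hspa4 at -0.14 ± 0.08 and Chordc1 at 0.15 ± 0.10. Clock and clock output genes did not pass either (10 of 19 higher, median 0.05, adjusted p = 0.452). Wee1 stood at 0.23 ± 0.07, Arntl at -0.36 ± 0.12 and Dbp at 0.22 ± 0.10. Lists for tissue that a liver sample can carry along did not pass. Pancreatic acinar genes had 12 of 15 members higher (median 0.05, adjusted p = 0.057; past 0.05 in 3 refits, the lowest 0.0425 without wild-type mouse 15), among them Cel at 0.18 ± 0.05, Cela1 at 1.04 ± 0.41 and Prss2 at 0.09 ± 0.05. Skeletal muscle genes had 7 of 14 higher (median -0.00, adjusted p = 0.957). Pvalb stood at -0.15 ± 0.10, Tnnt3 at 0.07 ± 0.05 and Myh1 at 0.06 ± 0.05. Erythroid genes had 5 of 10 higher (median -0.01, adjusted p = 0.827). Epor stood at 0.15 ± 0.07, Slc4a1 at -0.23 ± 0.15 and Epb42 at -0.20 ± 0.13. The erythroid median was 0.41 in wild-type mouse 22, against -0.19 to -0.01 in the other 4 wild types. The signs of the median, the mean and the camera test differed in 7 of the 39 lists, none of which passed: oxidative phosphorylation, citric acid cycle, erythroid, NADPH-producing, cholangiocyte, pentose phosphate and skeletal muscle genes.

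A knockout can carry a stretch of foreign DNA around the altered gene, so the genes next to Me1 on chromosome 9 were compared with all others. None of the 100 nearest measured genes, 50 on each side, passed adjusted p 0.05 in limma, against 6 of 19706 elsewhere (Fisher's exact test, two-sided, p = 1.0). With only 6 such genes among 19706, a count of 0 in the nearest 100 was nearly fixed in advance, so that comparison decides nothing. At an unadjusted p of 0.05 the counts were 6 of 100 and 2238 of 19706 (11.4%), with an exact p of 0.112. The densest stretch of genes at an unadjusted p under 0.01, 13 of 50 from Mras to Twf2, also lay on chromosome 9. It is described under the other observations.

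In the 5 wild-type arrays against the pool no feature passed adjusted p 0.05 in limma, and 161 (0.445%) had an unadjusted p under 0.05. A pool of other mice would leave about the share of features that the threshold of 0.05 itself allows, or more. The 0.445% seen argues against such a pool. If the pool was made of these 5 mice, their mean lies near 0 by construction, so this count is no measure of background for the knockout arrays. The 3 knockout arrays against the same pool gave 215 features past adjusted p 0.05, 50 higher and 165 lower (165 higher and 50 lower with the sign turned), of which 8 were among the 10 of the main comparison; both counts use the same knockout arrays, and the fit against the pool leaves out the spread between wild-type mice.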

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

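The tests of the 10 features and of the 18 lists, the exact permutation of list means, and those of mouse 15 and of clock genes for the cholesterol list were set only after the result was seen, while the splits of the cholesterol list were not. Among 159 values looked at in the 5 wild-type mice (120 genes and 39 list medians), 3 had 1 mouse far from the other 4 by Dixon's test, where chance gives about 1 in 20, or 7.95. Hspa4 was -0.21 in mouse 22 against 0.02 to 0.06 in the others (ratio of gap to range 0.871), Manf was 0.34 in mouse 22 against -0.16 to -0.07 (0.808), and Ldha was 0.37 in mouse 26 against -0.06 to 0.04 (0.759). The group of 3 knockouts is too small for this test.

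For the count of 10 features, only the real one of the 56 splits of the 8 mice gave as many, and the highest of the others gave 2. Prdm13, Vmn1r148, Car7 and the other 7 features all still passed without the wide array of wild-type mouse 22, and 65 features passed in that fit.

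The 18 gene lists were weighed next. The real split gave 18 and the highest other split 17, so 1 of 56 splits gave as many. That share is the smallest the 56 splits can give, but it rests on a margin of a single list, and further splits gave 16 and 15. The test was also set after the result was seen, so chance is not excluded for the count. Nor is chance excluded for any single list once adjusted over the 39, as given next. That members of a list vary together from mouse to mouse is a candidate explanation of the count, and 0 lists passed once that correlation was estimated. That 0 cannot settle it, because the estimated setting raised p even where the correlation was near the preset 0.01. The adipocyte list, with an estimated correlation of 0.0117, went from an unadjusted camera p of 0.0375 to 0.0848. An exact permutation of each list's mean over the 56 splits left 0 lists past adjusted p 0.05, with a lowest adjusted p of 0.174; 4 lists reached the smallest p possible, 0.0179, namely acute phase proteins, adipocyte genes, apolipoproteins and bile acid genes.

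For the rise of cholesterol synthesis genes, 2 of the 56 splits gave a mean difference as large in size, the real one at 0.95 and one that set wild-type mice 14, 15 and 22 apart at 1.04 in size, for an exact p of 0.0357. Chance is thus unlikely for this list taken alone, but adjusted over the 39 lists that p was 0.279, so chance is not excluded for a list picked out of 39. The low values of wild-type mouse 15 do not account for it, as the mean difference was 0.83 without that mouse. Among clock genes the largest difference was 0.44, for Per2, against a lower quartile of 0.72 for the cholesterol genes. Since no table tells how far clock genes would move with a given change in cholesterol genes, and Arntl stood at -0.36 ± 0.12, opposite to Per2, another time of day stays open. Feeding before sampling was not tested and stays open too, beside the genotype, and the members may act as a single measurement given their correlation of 0.661.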

How the results depend on the processing

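The turned sign, the removal of both widest arrays and the exact permutation of list means were chosen after seeing the data. The count of 10 features was also 10 with array medians at 0, with robust moderation and without features at the table's limits, 9 with a fold of 1.5, 8 with the knockout sign turned, and 7 with quantile normalization or among named genes alone. With each probe tested separately 16 probes passed, 2 of them listed for Vmn1r148. Among the 16 were 1 probe of Acpp (-1.15, limma adjusted p = 0.00255) and 1 of Ppp2r3a (-0.50, 0.0248), whose other probes did not pass. Lncbate1 (-1.70) and Slc10a2 (0.76) passed there too (both 0.0453). The count was 17 without the least variable features and 4 by the per-gene test without moderation. It was 26 at adjusted p 0.1 and 3355 at an unadjusted p of 0.05, and these 2 moved by construction. It was 207 with array weights, 215 for the knockout arrays against the pool and 19 without both widest arrays. The cause of the other moves was not tested; the lowest and highest counts with 1 mouse left out were 6 (wild-type mouse 14) and 65 (wild-type mouse 22). Array weights kept all 10. Lists past the threshold numbered 14 to 17 with 1 mouse left out and 15 to 21 in the other fits with a preset correlation, but 0 with an estimated correlation, 0 by fry and 0 by exact permutation. Of the 18 lists, 8 kept their call and direction in all 16 refits with a preset correlation and unturned sign, cholesterol synthesis among them, and 5 lists that had not passed did so in some refits. The Me1 difference of 0.09 reversed to -0.53 with array weights, to -0.22 for the knockout arrays against the pool, and ranged from -0.43 to 0.38 with 1 mouse left out; it passed no test. Wild type against the pool gave 0 in every fit but 2 features without wild-type mouse 22. The 119 single genes other than Me1 that the rule fixed beforehand names had 2137 values, none with the sign turned and without the genes named later. Of these values, 2082 kept direction and side, 26 lost their call, 28 gained one, and 1 reversed. The reversal was Zfy1, at -0.0052 without knockout mouse 27 and up to 0.23 without knockout mouse 33. The reversals of Me1 given above are not in this count. No value was missing, so the rule for missing values was not run. For the list counts, the settings that do not enter camera were not run either. Signal over background was not used here.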

Other observations

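The tests of gene order by shuffling, of the genes nearest to Me1 and of genes in 2 clusters were chosen only after the result was seen, while the test over the 56 splits was not. Single genes differed widely among the 5 wild-type livers. The 10 named genes of widest spread were 5330434G04Rik, Hsd3b5, Hsd3b4, Ndufaf2, Scara5, Slco1a1, Cyp2b13, Rnase2a, Hddc3 and Cyp17a1. 5330434G04Rik ran from -6.64 in mouse 22, the lowest value the table holds, to 3.33 in mouse 14. The steroid dehydrogenases Hsd3b5 and Hsd3b4 ran from -4.03 to 1.61 and from -3.63 to 1.67 on the log2 scale, lowest in mouse 26 and highest in mouse 22. Slco1a1 ran from -3.08 in mouse 26 to 1.18 in mouse 22, Cyp2b13 from -3.41 in mouse 22 to 1.13 in mouse 15, and Cyp17a1 from -3.14 in mouse 21 to 1.19 in mouse 26. Hddc3 was 1.85 in mouse 22 and between -1.87 and -1.69 in the other 4 wild types, while the knockouts had 0.64, 1.68 and 1.26.

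Single genes short of the threshold in the comparison of all 8 mice, at limma adjusted p between 0.05 and 0.1, included Lncbate1 at -1.70 ± 0.19 (adjusted p = 0.0541), the glutathione peroxidase gene Gpx6 at 0.78 ± 0.09 (0.0677), the tight junction gene Cldn5 at 0.44 ± 0.05 (0.0716) and Lcn2 at -1.79 ± 0.23 (0.0829).

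Genes that differed between the genotypes lay near one another on chromosomes. With 617 of 19807 placed genes (3.12%) at an unadjusted p under 0.01, a window of 50 genes should hold 1.56. The densest window held 13, on chromosome 9 (Ppp2r3a, Ephb1, Acpp and Nudt16 among them, 4 higher and 9 lower), followed by 12 on chromosome 6 (Pik3c2g, Plbd1, Emp1 and Hebp1 among them) and 11 on chromosome 7 (Zfp383, Zfp74 and Lgals4 among them). Random placement is unlikely, since none of 1000 shuffled orders reached 13 and their highest was 10 (permutation p = 0.000999, the smallest they can give). The window size and the p threshold were chosen after others were looked at. The shuffles test the order of genes only and tell nothing about the genotype. The window is not particular to the real split: 8 of the 56 splits, taken at the same number of genes, had one at least as dense, up to 15, on chromosomes 1, 6, 9, 13 and 18. Neighbouring genes that vary together whatever the genotype may therefore be a source of the pattern, and DNA segments that differ between littermates of mixed descent are a candidate explanation that no genotype data tested here. A segment carried along with the Me1 allele cannot explain the 12 genes on chromosome 6, while for chromosome 9 it cannot be told apart from other explanations: the 100 genes nearest to Me1 held 1 gene at that p, 1.0% against 3.13% elsewhere (Fisher's exact p = 0.379), and no genotypes were used here.

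Some genes split the 8 mice into 2 tight clusters at least 0.8 apart on the log2 scale, each of at least 2 mice. Of 11 such genes, the clusters were the 2 genotypes in Prdm13 and Vmn1r148. In 4 of the other 9 they divided the knockouts: Agbl2 was high in wild-type mouse 26 and knockout mice 27 and 31 (gap 2.04), Psmc3ip in wild-type mouse 14 and knockout mouse 27 (gap 1.94), Tm7sf3 in wild-type mouse 26 and knockout mouse 27 (gap 1.11) and Cep85 in knockout mice 31 and 33 (gap 0.80). In the other 5 all 3 knockouts lay in 1 cluster together with wild types. Eda2r was low in them and in wild-type mouse 22 (gap 1.41), and Rerg was high in them and in wild-type mouse 26 (gap 0.87). Apoe was high only in wild-type mice 15 and 21 (gap 1.33), Irgm2 only in wild-type mice 14, 21 and 22 (gap 1.06), and Gstm6 was low only in wild-type mice 14, 15 and 22 (gap 0.88).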
